A study of Drosophila melanogaster with 6 samples.

How the data were processed

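Total RNA of adult fly heads was measured on Affymetrix expression arrays, 3 arrays from heads at 2 days and 3 from heads at 25 days, of a single genotype. Per the labels' protocols, flies were frozen before their heads were collected, RNA was extracted with Trizol and biotin-labelled by Affymetrix's standard method. The values are RMA expression values on the log2 scale as deposited by the authors; RMA and limma are named by the submitters' processing notes, and their versions and settings are not given in the sources used here. RMA subtracts background, normalizes the arrays to a common distribution and summarises the probes of each probe set. The values ranged from about 2 to about 14, with near-equal medians and quartiles on all arrays, as values after between-array normalization do. Such scaling sets aside any change in the total amount of messenger RNA per head. Levels near the bottom of the range are background, so a fold or difference that starts or ends there is compressed and is a lower bound.

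The 18952 probe sets included 183 controls, which stayed out of all tests, leaving 18769. Genes were named from the platform's probe table, in which 13646 tested probe sets had 1 gene symbol, 402 had several and 4721 had none here; a probe set with several or no symbols was tested and left unnamed. Of those with 1 symbol, 13543 matched the RefSeq table (Release 6 plus ISO1 MT) by gene identifier and 103 kept the probe table's symbol; 0 symbols changed. The assembly served only for names, since no build was given for the array, and no coordinates are printed. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it, 11982 genes in all. Counts for a gene list cover only its genes with a probe set of their own.

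Aged and young arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariates, all 6 arrays), and p-values were adjusted over all probe sets with the Benjamini-Hochberg method at 0.05. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, for lists with at least 5 measured genes, adjusted over 27 lists. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. In writing down the lists, the patterns for mitochondrial ribosomal proteins, for glutathione S-transferases other than Mgstl and for further subunits of the proteasome's core particle were lost by a slip. The first of these lists was left empty and the second, with Mgstl alone, was not tested (Mgstl differed by -0.05 ± 0.07 on the log2 scale and did not pass, while its other probe set stood at 0.31). Those families, and lists of chitin genes, ionotropic and gustatory receptors, vacuolar ATPase, tubules, CheA and CheB genes and flight muscle, were added after the data were seen and appear only as such.

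The rule for named genes takes the 10 largest rises and the 10 largest falls among genes that passed, whose ages did not overlap and whose higher mean was at or above the median level of all probe sets (4.92), and from each list up to 3 members with the largest difference among those that passed at that level, or otherwise the 1 with the smallest p. It named 102 genes, of which 99 passed. Where 5 or fewer members of a list passed in a direction, all are named; those outside the rule, and Drs, Ms, NPF, Obp56e, Obp28a, Obp83cd, fln, TpnC4 and the further members of the added lists, were chosen after their values were seen, and were not tested with arrays left out. Members of lists for other tissues were given as counts and medians unless they passed or the closing section needed the levels of the most abundant.

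RNA quality was read as the mean difference between 3' and 5' probe sets of control transcripts and tested with a two-sided exact permutation test. On simulated data with the spread of these arrays, limma recovered 42% of 100 probe sets changed by 0.5 and 91% of 100 changed by 1 on the log2 scale, and 5 of 138 calls (3.62%) were false; the list test found the 1 list shifted by 0.3 and 0 of 26 others. These simulated arrays have independent probe sets, so that 0 does not bear on correlated lists. Far fewer probe sets were changed in the simulation than passed in the real data (138 calls against 4071). The adjusted threshold was therefore stricter there, and the shares recovered are not the sensitivity of the real comparison. The alternatives were limma-trend with a robust prior, a filter at the median level, centring of arrays on their medians, quantile normalization, array weights, leaving out probe sets with IDs ending in _s_at or _x_at, which can be shared between genes, and in _a_at, which are shared by transcripts of 1 gene, 1 probe set per gene, the replicate number as a block, a test against a 2-fold threshold, other list tests, and leaving out each array in turn. Leaving out young replicate 2 and aged replicate 3 together, adding the lost families to the lists, list tests without _s_at and _x_at probe sets alone, and control transcripts with 18S rRNA or the bacterial spike-ins in place of the fly transcripts were added after the data were seen.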

Results

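Whole heads of adult Drosophila melanogaster were compared at 2 ages, 2 days (young) and 25 days (aged). The flies carried P{GawB}elavC155, an enhancer-trap insertion at the neuronal gene elav that drives the yeast activator GAL4. RNA from heads was labelled with biotin and hybridised to Affymetrix arrays, 3 arrays per age, and expression was read as RMA values on the log2 scale, on which a difference of 1 is a 2-fold change. The labels do not say that the arrays of an age came from separate collections of flies, so p-values measure only the spread between these arrays, which may be technical. The labels do not give the sex of the flies. The small number of arrays limits the precision. Array medians lay between 4.85 and 4.93 over 18769 probe sets.

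Arrays of 1 age resembled each other more than arrays of different ages. Pearson's r across probe sets, which are not independent replicates, was 0.991 to 0.998 in the 6 pairs of the same age and 0.984 to 0.9895 in the 9 pairs of different ages. The first principal component held 60.2% of the variance and separated the ages, and the second held 20.95% and set young replicate 2 apart. Young replicate 2 exceeded every other array by at least 1 on the log2 scale at 155 probe sets, aged replicate 3 did so at 25, young replicate 3 at 2, and the other arrays at 0.

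Aged heads had higher levels of 8 of 14 measured antimicrobial peptide genes than young heads, and lower levels of most measured genes of the respiratory chain and of synaptic vesicle release. These lists shifted with camera's preset correlation but not with an estimated correlation (adjusted p = 0.268 to 0.269). Genes on the list of odorant-binding proteins and olfactory receptors went both ways, with 4 that rose and 6 that fell, and 22 of 105 cuticle protein genes fell. Of the genes that met the naming rule, CAH5 (CG18673), a carbonic anhydrase, rose most, from 3.72 ± 0.25 to 8.91 ± 0.21 (mean log2 value ± SD, n = 3 arrays), or at least 36.7-fold. It was followed by Def (CG1385), which encodes the antimicrobial peptide defensin and rose 18-fold, and by the odorant-binding protein gene Obp56a (CG11797), which rose 14.3-fold. The steepest falls were those of CG7214, from 12.28 ± 0.18 to 4.23 ± 0.14 or at least 266-fold, and CG11458, which fell at least 70.6-fold from 10.85 ± 0.03 to 4.71 ± 0.05. The folds of CAH5, CG7214 and CG11458 are lower bounds, since the lower level lies below the median of all probe sets (4.92), near background. The ages also differed in the 3' minus 5' difference of control transcripts, which was lower on all aged arrays than on all young arrays, by 0.52 in fly transcripts and by 0.90 in bacterial spike-ins. Labelling and age cannot be told apart in it. The same limit holds for the gene differences, since the genes were labelled on the same arrays.

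Of 18769 probe sets, 4071 (21.7%) differed between the ages, 2438 higher and 1633 lower in aged heads (limma, Benjamini-Hochberg adjusted). The changes were mostly small. The median absolute difference of the changed probe sets was 0.43 on the log2 scale, and 292 of them changed at least 2-fold, 170 up and 122 down. By genes, each read through a single probe set, 3177 of 11982 changed, 1892 up and 1285 down. Arrays of the ages did not overlap at 7665 probe sets (40.8%), where chance gives 10%. The share of changed probe sets that were higher, 59.9%, was 48.8% with each array centred on its median, when 3810 changed. Without aged replicate 1 the count was 2302 (1377 up, 925 down), and without aged replicate 2 it was 2432 (1460 up, 972 down). With young replicate 2 and aged replicate 3 both left out, a choice made after seeing the data, it was 2492 (1462 up, 1030 down). Only 59 probe sets passed a test against the 2-fold threshold itself.

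The other large rises were those of CG4783 (3.31 ± 0.27 log2, difference ± SE, limma adjusted p = 4.52e-04), CheA87a, of a family of chemosensory proteins of taste bristles (3.26 ± 0.39, adjusted p = 0.00191) and DptB (3.05 ± 0.24). They were followed by CG9377 (2.91 ± 0.16), the long non-coding RNA lncRNA:CR32368 (2.47 ± 0.16), the olfactory ionotropic receptor gene Ir75a (2.42 ± 0.10) and Mtk (2.38 ± 0.16). For Obp56a and CheA87a, aged replicate 3 was the highest array, and the differences without it were 3.29 and 2.87. The other large falls were those of CG8736 (-4.84 ± 0.18), Vajk3 (-4.11 ± 0.17), Vajk2 (-3.66 ± 0.11, with -1.66 at its other probe set) and CG4000 (-3.29 ± 0.09). After them came the cuticle protein gene Cpr100A (-3.28 ± 0.10), CG13026 (-3.26 ± 0.16), CG7203 (-3.19 ± 0.08) and the cuticle protein gene Cpr62Bc (-2.72 ± 0.14). For CG4783, CG8736, Vajk3 and Cpr62Bc the lower level lies below the median of all probe sets, so their differences are lower bounds.

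**Figure D1:**
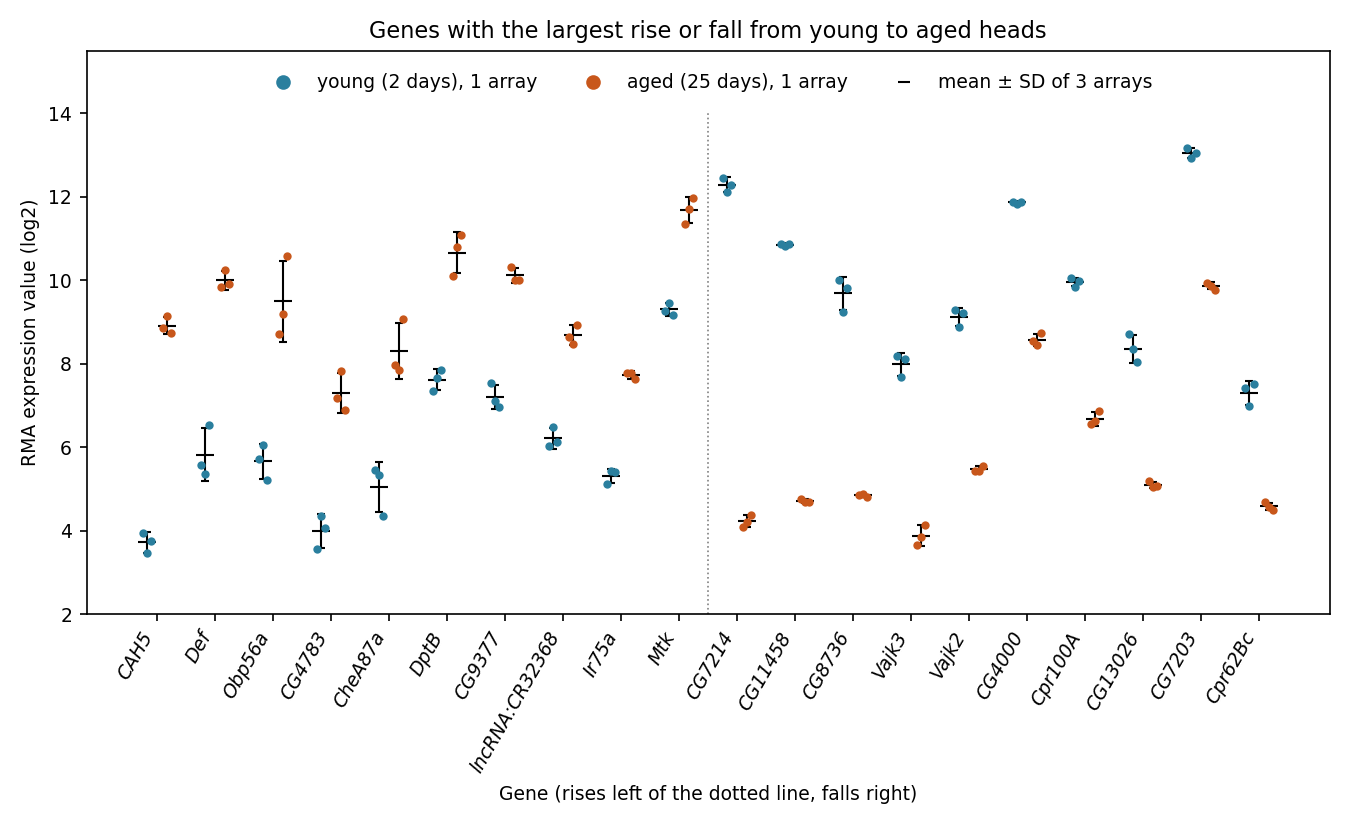
RMA expression values (log2, vertical axis) of the 10 genes with the largest rise and the 10 with the largest fall (horizontal axis), with a point per array, blue for young and orange for aged heads, and bars for the mean ± SD of 3 arrays. Genes whose ages overlap were left out by the naming rule. Means run from CAH5 (3.72 young, 8.91 aged) to CG7214 (12.28 young, 4.23 aged).

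The immune genes of both lists that passed over all probe sets were higher in aged heads. Of 29 antimicrobial peptide genes on the list, 14 had a probe set of their own. Of these 14, 8 rose, 0 fell and 6 did not pass over all probe sets, against 9 higher and 1 lower adjusted over the list alone. Def rose by 4.17 ± 0.29, DptB, a diptericin, by 3.05 ± 0.24, and Mtk, which encodes metchnikowin, by 2.38 ± 0.16, whereas Drs, which encodes drosomycin, differed by -0.69 ± 0.24 and did not pass (adjusted p = 0.0883). The list as a whole shifted up (camera adjusted p = 0.00219, and adjusted p = 0.268 with an estimated correlation). Of 28 genes of immune recognition and signalling, 17 rose, 0 fell and 11 did not pass over all probe sets, against 20 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.27e-06, and adjusted p = 0.268 with an estimated correlation). The secreted peptidoglycan recognition protein gene PGRP-SB1 rose 4.0-fold (2.00 ± 0.10, adjusted p = 7.02e-05), pirk, a negative regulator of the Imd pathway, 3.99-fold, and PGRP-LB, which encodes a peptidoglycan-degrading amidase, 2.39-fold.

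Among the cytochrome P450, proteasome and ribosomal protein genes that passed, most were higher in aged heads. Among 80 cytochrome P450 genes, 32 rose, 4 fell and 44 did not pass over all probe sets, against 36 higher and 7 lower adjusted over the list alone. Cyp4e3 (1.86 ± 0.19), Cyp4d1 (1.56 ± 0.09) and Cyp6w1 (1.34 ± 0.11) rose most, and the 4 that fell were Cyp4ae1 (-1.07), Cyp4c3 (-0.91), Cyp18a1 (-0.36) and Cyp49a1 (-0.25, below the median level at both ages) (camera adjusted p = 2.04e-05, and adjusted p = 0.102 with an estimated correlation). Of 21 proteasome genes, mostly of the regulatory particle, 16 rose, 0 fell and 5 did not pass over all probe sets, against 19 higher and 0 lower adjusted over the list alone, with Prosalpha3 (0.60 ± 0.07), Rpt2 (0.43 ± 0.08) and Prosalpha7 (0.43 ± 0.06) the highest (camera adjusted p = 5.41e-07, and adjusted p = 0.260 with an estimated correlation). Of 86 cytosolic ribosomal protein genes on the list, 34 had a probe set of their own. Of these 34, 8 rose, 0 fell and 26 did not pass over all probe sets, against 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.95e-04, and adjusted p = 0.307 with an estimated correlation). RpS5b, whose young level of 4.54 lay below the median of all probe sets, rose by at least 0.80 ± 0.08. RpS7 rose by 0.47 ± 0.06 and RpS18 by 0.28 ± 0.06. A different probe set of RpS7 stood at -0.27, and RpS18 no longer passed when any single aged array was left out (adjusted p = 0.0536 to 0.0624) or without young replicate 2 and aged replicate 3 together (0.0851).

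The lists of autophagy and stress genes did not pass with camera on all 6 arrays. Of 24 autophagy genes, 5 rose, 1 fell and 18 did not pass over all probe sets, against 7 higher and 1 lower adjusted over the list alone. Mitf, a transcription factor of lysosomal genes, rose by 0.92 ± 0.11 and the autophagy receptor gene ref(2)P by 0.48 ± 0.07. Atg10, below the median level at both ages, rose by 0.58 ± 0.09, Atg3 by 0.32 ± 0.08 and Atg14 by 0.28 ± 0.06, and Atg1 fell by 0.22 ± 0.07 (camera adjusted p = 0.0682, and adjusted p = 0.269 with an estimated correlation). The autophagy list passed, upwards, with fry (adjusted p = 0.00162) and with camera without young replicate 1 (0.0497). Of 26 heat shock protein and chaperone genes on the list, 14 had a probe set of their own, and the rest were not measured. Of these 14, 2 rose, DnaJ-1 (0.29 ± 0.08) and Hsc70-4 (0.29 ± 0.07), 0 fell and 12 did not pass, against 1 higher and 0 lower adjusted over the list alone. At an unadjusted limma p under 0.05, 4 were higher and 1 lower (camera adjusted p = 0.816). The list's test pointed up, or down above the median level alone (adjusted p = 0.946), without _s_at, _x_at and _a_at probe sets (0.711) or the first 2 of these (0.7265), without aged replicate 3 (0.7645), and without young replicate 2 and aged replicate 3 together (0.730). Of 19 genes of oxidative stress defence, 2 rose, 2 fell and 15 did not pass over all probe sets, against 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.854). The mitochondrial superoxide dismutase gene Sod2 (-0.54 ± 0.06) and the methionine sulfoxide reductase gene SelR (-0.35 ± 0.06, with 0.03 at its other probe set) fell. Keap1 (0.29 ± 0.07) and cnc (0.27 ± 0.07), which encode an oxidative stress sensor and its transcription factor, rose. The list's median (0.04) and mean (0.0058) lay above 0, while its test pointed down, or up without young replicate 1 (adjusted p = 0.945). The call of DnaJ-1 or of Keap1 was lost without any single array other than young replicate 1 (adjusted p = 0.0548 to 0.154 and 0.0516 to 0.0810). That of Atg3 was lost without young replicate 2 or 3 or aged replicate 1 or 2 (0.0522 to 0.0937), and that of Hsc70-4 without young replicate 3 or aged replicate 1 or 3 (0.0622 to 0.0703). Median centring ended the calls of DnaJ-1 (0.0876), Keap1 (0.0675) and Atg3 (0.0550). Quantile normalization ended those of DnaJ-1 (0.0518), Hsc70-4 (0.0716) and Keap1, whose difference was then 0.17 (0.151). Without young replicate 2 and aged replicate 3 together, DnaJ-1 (0.20), Hsc70-4 (0.0960) and Keap1 (0.143) did not pass.

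Most genes of the mitochondrial respiratory chain fell, by small amounts. Of 27 genes of complex I, 0 rose, 22 fell and 5 did not pass over all probe sets, against 0 higher and 24 lower adjusted over the list alone, with a median difference of -0.36 (camera adjusted p = 2.97e-11, and adjusted p = 0.268 with an estimated correlation). ND-B18 (-0.64 ± 0.06), ND-19 (-0.63 ± 0.07) and ND-42 (-0.59 ± 0.07) fell most, and at an unadjusted limma p under 0.05, 0 members were higher and 24 lower. Of 27 genes of complexes III to V, 1 rose, 23 fell and 3 did not pass over all probe sets, against 1 higher and 23 lower adjusted over the list alone, with a median of -0.41 (camera adjusted p = 5.56e-11, and adjusted p = 0.268 with an estimated correlation). The ATP synthase subunit gene ATPsyngamma (-0.71 ± 0.06) and the cytochrome c oxidase subunit gene COX5B (-0.65 ± 0.08) fell, while UQCR-11, of complex III, rose by 0.89 ± 0.07. The probe set of UQCR-11 was dim, with a young level of 4.93, close to the median of all probe sets (4.92), and an aged level of 5.82. Of 14 glycolytic genes, 1 rose, 6 fell and 7 did not pass over all probe sets, against 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0258, and adjusted p = 0.268 with an estimated correlation). The list did not pass without probe sets whose IDs end in _s_at, _x_at or _a_at (adjusted p = 0.0626, 7 genes, median -0.22). Leaving out only _s_at and _x_at, a choice made after seeing the data, it passed (adjusted p = 0.0158, 9 genes, median -0.26). Gapdh1 (-0.49 ± 0.06), Pfk (-0.40 ± 0.08) and Gpdh1 (-0.39 ± 0.08, with -0.59 to -0.08 over 4 probe sets, 2 of which passed) fell and the trehalase gene Treh (0.39 ± 0.07) rose. Gpdh1 no longer passed without aged replicate 1 or aged replicate 3 (adjusted p = 0.0588 and 0.0515), or without young replicate 2 and aged replicate 3 together (0.0641). Of 13 genes of the citric acid cycle, 2 rose, 6 fell and 5 did not pass over all probe sets, against 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.101). This list passed, downwards, above the median level alone (adjusted p = 0.0490), without aged replicate 3 (0.0344), without _s_at and _x_at probe sets (0.0172) and without young replicate 2 and aged replicate 3 together (0.0467), but not with an estimated correlation (adjusted p = 0.607). The succinate dehydrogenase gene SdhD (-0.59 ± 0.07) and Idh3a (-0.55 ± 0.07) fell, and ScsbetaA (0.45 ± 0.06) and Idh (0.22 ± 0.06) rose.

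Most of the genes of transmitter release, synthesis and transport that passed were lower in aged heads. Of 23 genes of synaptic vesicle release, 1 rose, 18 fell and 4 did not pass over all probe sets, against 2 higher and 20 lower adjusted over the list alone, with a median of -0.38 (camera adjusted p = 3.95e-07, and adjusted p = 0.269 with an estimated correlation). The dynamin gene shi (-0.90 ± 0.10, with -0.90 to -0.27 over 3 probe sets, 2 of which passed), the synapse-associated protein gene Sap47 (-0.81 ± 0.06, with -0.21 at its other probe set, which did not pass) and the calcium sensor gene Frq1 (-0.79 ± 0.10) fell most, and Liprin-alpha rose by 0.49 ± 0.06. Of 19 genes of neurotransmitter synthesis and transport, 1 rose, 12 fell and 6 did not pass over all probe sets, against 2 higher and 12 lower adjusted over the list alone (camera adjusted p = 2.06e-05, and adjusted p = 0.268 with an estimated correlation). Pu, which encodes GTP cyclohydrolase, fell 2.03-fold (-1.02 ± 0.07, adjusted p = 2.55e-04), and the vesicular acetylcholine transporter gene VAChT (-0.76 ± 0.08) and the choline transporter gene ChT (-0.69 ± 0.08) fell with it, whereas Ace, which encodes acetylcholinesterase, rose by 0.36 ± 0.08. Neuropeptide genes went both ways. Of 27, 8 rose, 5 fell and 14 did not pass over all probe sets, against 9 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.629). Nplp3 (-1.30 ± 0.10), SIFa (-1.30 ± 0.08), Nplp4 (-0.73 ± 0.08), the insulin-like peptide gene Ilp5 (-0.62 ± 0.09) and CCHa2 (-0.39 ± 0.10) fell, and the 8 that rose did so by 0.33 (Ms) to 0.63 (NPF).

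Sensory genes changed in both directions. Of 25 phototransduction genes, 4 rose, 9 fell and 12 did not pass over all probe sets, against 4 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.648 with an estimated correlation; adjusted p = 0.0558 without aged replicate 3). The scavenger receptor gene ninaD, needed for carotenoid uptake, fell at least 2.71-fold, and eys, which encodes an extracellular protein of the space between rhabdomeres, 2.57-fold at its brightest probe set, though its 4 probe sets ranged from -1.36 to -0.05 and only that probe set passed. The genes that rose were ninaG, which acts in rhodopsin chromophore synthesis (0.84 ± 0.08), Pph13 (0.35 ± 0.07), Gprk1 (0.29 ± 0.07) and santa-maria (0.25 ± 0.07). Other than Rh7, no rhodopsin gene was found under its name in the probe table, nor was norpA, so they were not analysed here; whether an unnamed or shared probe set measures them was not examined. Among 32 genes on the list of odorant-binding proteins and olfactory receptors, 4 rose, 6 fell and 22 did not pass over all probe sets, against 5 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.854). All olfactory receptor genes on it, Orco among them (4.50 young, 4.57 aged), lay below the median level at both ages, near background. That they did not pass therefore does not show that they were unchanged. Some brighter genes that did not pass varied widely between arrays of the same age. Obp83b ran from 4.93 to 7.24 on young and from 5.71 to 7.29 on aged arrays, and Os-C from 4.44 to 6.14 and from 4.83 to 6.32. Obp56a (3.84 ± 0.45), Obp83ef (at least 1.49 ± 0.11, with a young level below the median), a10 (1.29 ± 0.22) and Obp57c (0.42 ± 0.09) rose. Obp56e (-1.15 ± 0.11), Obp28a (-0.91 ± 0.23) and Obp83cd (-0.68 ± 0.08) had the largest of the 6 falls. The list's median (0.03) and mean (0.15) lay above 0 while the test pointed down. Its direction turned up with median centring (adjusted p = 0.966) or quantile normalization (0.946), without young replicate 2 (0.808) or aged replicate 1 (0.853), and without young replicate 2 and aged replicate 3 together (0.730). On aged replicate 3, 12 of 12 CheA and CheB genes lay above the other aged arrays, with a median excess of 2.11.

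The list of cuticle protein genes shifted down, though most of its genes did not pass. Of 105 measured, 3 rose, 22 fell and 80 did not pass over all probe sets, against 3 higher and 23 lower adjusted over the list alone, with a median of -0.16 (camera adjusted p = 7.10e-06, and adjusted p = 0.367 with an estimated correlation). Cpr100A fell 9.71-fold, Cpr62Bc at least 6.60-fold and Cpr49Ae 4.54-fold, and the 3 that rose were Cpr67B (0.48 ± 0.07), Cpr72Ec (0.46 ± 0.10) and TwdlG (0.32 ± 0.09). Of 21 muscle genes, 0 rose, 11 fell and 10 did not pass over all probe sets, against 0 higher and 12 lower adjusted over the list alone, with a median of -0.79 (camera adjusted p = 3.71e-06, and adjusted p = 0.439 with an estimated correlation), and at an unadjusted limma p under 0.05, 0 were higher and 15 lower. The actin genes Act88F (-2.17 ± 0.21) and Act79B (-1.76 ± 0.43) and the myosin light chain gene Mlc2 (-1.39 ± 0.18) fell most. The muscle list stood 0.58 higher on aged replicate 3 than on the other aged arrays, as a median excess, and its median difference was -0.91 without that array, -0.48 without young replicate 2 and -0.72 without both. The list did not pass without probe sets whose IDs end in _s_at, _x_at or _a_at (camera adjusted p = 0.112), which left 11 genes with a median of -0.18. Leaving out only _s_at and _x_at, a choice made after seeing the data, left 18 genes with a median of -0.69 and the list passed (camera adjusted p = 2.22e-05). Act79B did not pass without young replicate 1 or 2 or aged replicate 1 or 2 (adjusted p = 0.0513 to 0.0934) or with limma-trend and a robust prior (0.106).

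**Figure D2:**
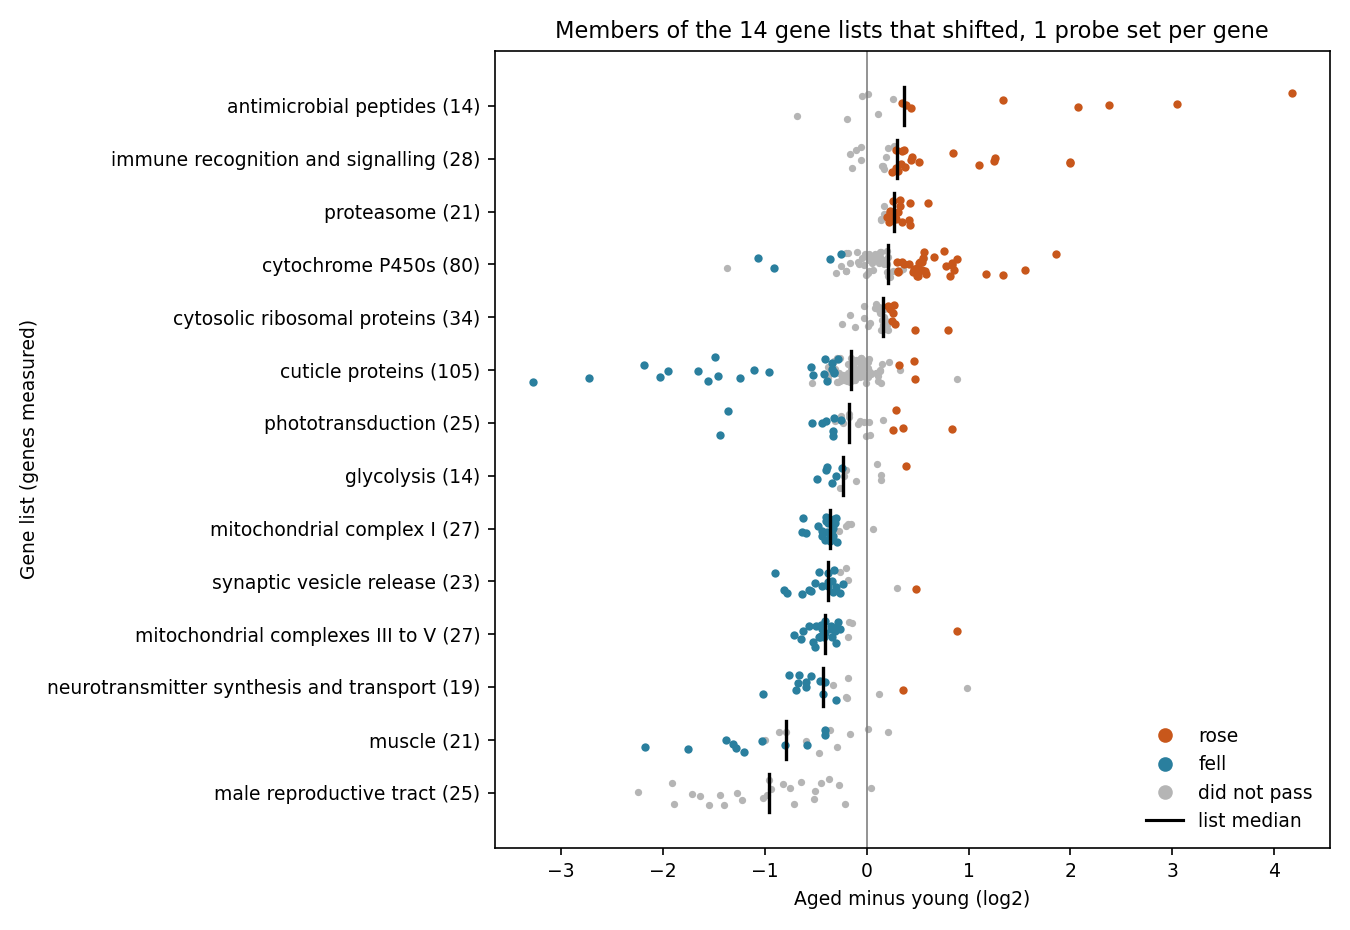
Difference between aged and young heads (log2, horizontal axis) of the members of the 14 gene lists that shifted with camera's preset correlation, 0 of which did with an estimated correlation (vertical axis, with the number of genes measured); points are genes, orange for those that rose, blue for those that fell and grey for those that did not pass, and black bars are list medians. Medians run from -0.96 for the male reproductive tract, none of whose members passed (-0.08 without young replicate 2), to 0.36 for antimicrobial peptides.

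Markers of glia, fat body and blood cells changed in both directions. Of 17 glial genes, 1 rose, 5 fell and 11 did not pass over all probe sets, against 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0682). The list passed, downwards, with limma-trend and a robust prior (adjusted p = 0.0445), above the median level alone (0.0255), with quantile normalization (0.04625), with fry (0.0136), without _s_at and _x_at probe sets (0.0275) and without young replicate 3 (0.0466) or aged replicate 1 (0.0413). It did not pass with an estimated correlation (adjusted p = 0.543). The immunoglobulin superfamily gene bdl (-1.20 ± 0.07), the sodium pump subunit gene nrv2 (-0.83 ± 0.08), the innexin gene Inx2 (-0.73 ± 0.09), alrm (-0.48 ± 0.06) and Gs2 (-0.38 ± 0.08) fell, and Gli (0.42 ± 0.08) rose. Of 15 fat body and female-biased secreted genes, 4 rose, 1 fell and 10 did not pass over all probe sets, against 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.702). The lipase gene bmm (0.71 ± 0.08), the lipid transfer protein gene Apoltp (0.70 ± 0.06), Mtp (0.47 ± 0.07) and Lsd-2 (0.25 ± 0.07) rose, and fit (-0.55 ± 0.11) fell, with adjusted p = 0.0504 without aged replicate 1. The list's median (-0.06) and mean (-0.11) lay below 0 while its test pointed up. Of 17 haemocyte genes, 6 rose, 2 fell and 9 did not pass over all probe sets, against 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0682). This list passed, upwards, with median centring (adjusted p = 0.0421), with fry (0.0485) and without young replicate 3 (0.0380) or aged replicate 1 (0.0309), but not with an estimated correlation (adjusted p = 0.543). The scavenger receptor gene Sr-CI rose by 0.75 ± 0.11, and NimC4 (-1.10 ± 0.19) and the peroxidasin gene Pxn (-0.90 ± 0.11, with -0.17 at its other probe set) fell. The aged level of NimC4 lay below the median of all probe sets, so its difference is a lower bound.

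Clock and chromatin genes changed in both directions. Of 13 circadian clock genes, 2 rose, 3 fell and 8 did not pass over all probe sets, against 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.822). Pdp1 (-0.57 ± 0.09), per (-0.53 ± 0.11) and dco (-0.26 ± 0.07) fell, and tws (0.35 ± 0.09) and Clk (0.24 ± 0.07) rose. The clock list's median was 0.08 and its mean -0.0041, while the test pointed up. It pointed down after quantile normalization (adjusted p = 0.945), above the median level alone (0.905) and without probe sets whose IDs end in _s_at, _x_at or _a_at (0.988). The labels give no time of day of collection. Of 23 Polycomb and Trithorax group genes, 3 rose, 2 fell and 18 did not pass over all probe sets, against 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.822). Psc (-0.59 ± 0.15) and Jarid2 (-0.27 ± 0.07) fell, and jing (0.40 ± 0.08, below the median level at both ages), ash2 (0.31 ± 0.07) and the chromatin assembly factor gene CG4236 (0.26 ± 0.06) rose. The list's median was 0.0018 and its mean -0.018. Its test pointed down, or up without young replicate 3 (adjusted p = 0.9115), with fry (0.936) and without young replicate 2 and aged replicate 3 together (0.830). Removing any single array other than young replicate 1 ended the calls of tws (adjusted p = 0.0534 to 0.109), Psc (0.0546 to 0.0852) and Jarid2 (0.0505 to 0.120), and that of ash2 ended without young replicate 3 or any aged array (0.050 to 0.0735), or with median centring (0.0515). Without young replicate 2 and aged replicate 3 together, per (0.0639), tws (0.0983), Psc (0.124), Jarid2 (0.136) and ash2 (0.0946) did not pass.

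Transcripts of tissues outside the head were raised on single arrays. The male reproductive tract list had a median level of 5.73 on young replicate 2 and of 2.90 to 3.07 on the other 5 arrays, and midgut digestive enzymes a level of 4.31 against 3.39 to 3.64. The list of 3 flight muscle genes, added after the data were seen, had a median of 6.04 on that array and of 3.56 to 3.71 on the others. Of 25 male tract genes, 0 rose, 0 fell and 25 did not pass over all probe sets, against 0 higher and 0 lower adjusted over the list alone, and 0 passed in either direction at an unadjusted limma p under 0.05. The list nevertheless shifted down (camera adjusted p = 0.00850, and adjusted p = 0.763 with an estimated correlation), with a median of -0.96 that was -0.08 without young replicate 2 (camera adjusted p = 0.0811). The ejaculatory bulb protein gene Ebp stood at 9.72 on that array and at 3.03 to 3.24 on the others. Its difference of -2.25 ± 1.62 (adjusted p = 0.369) was -0.06 without that array and -3.38 without young replicate 3. Of 28 midgut genes, 1 rose, 0 fell and 27 did not pass over all probe sets, against 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0508). This list passed, downwards, without young replicate 1 (adjusted p = 0.0420), young replicate 3 (0.00291) or aged replicate 1 (0.0466) and without _s_at and _x_at probe sets (0.0404) or these and _a_at (0.0204). It also passed with median centring (adjusted p = 0.0492), the replicate block (0.0283), the mean of all probe sets of a gene (0.0402), the rank version of camera (0.0217) and the restored families (0.047), but not with an estimated correlation (adjusted p = 0.722). Its median of -0.25 was -0.09 without young replicate 2. The gene that rose was the lysosomal mannosidase gene LManII (0.49 ± 0.07), which was bright on all arrays. Of 20 ovary and eggshell genes, 0 rose, 0 fell and 20 did not pass over all probe sets, against 0 higher and 0 lower adjusted over the list alone. At an unadjusted limma p under 0.05, 1 was higher and 1 lower. The gene gcl, with the smallest p of those bright enough to be named, differed by 0.15 ± 0.06 (camera adjusted p = 0.336).

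**Figure D3:**
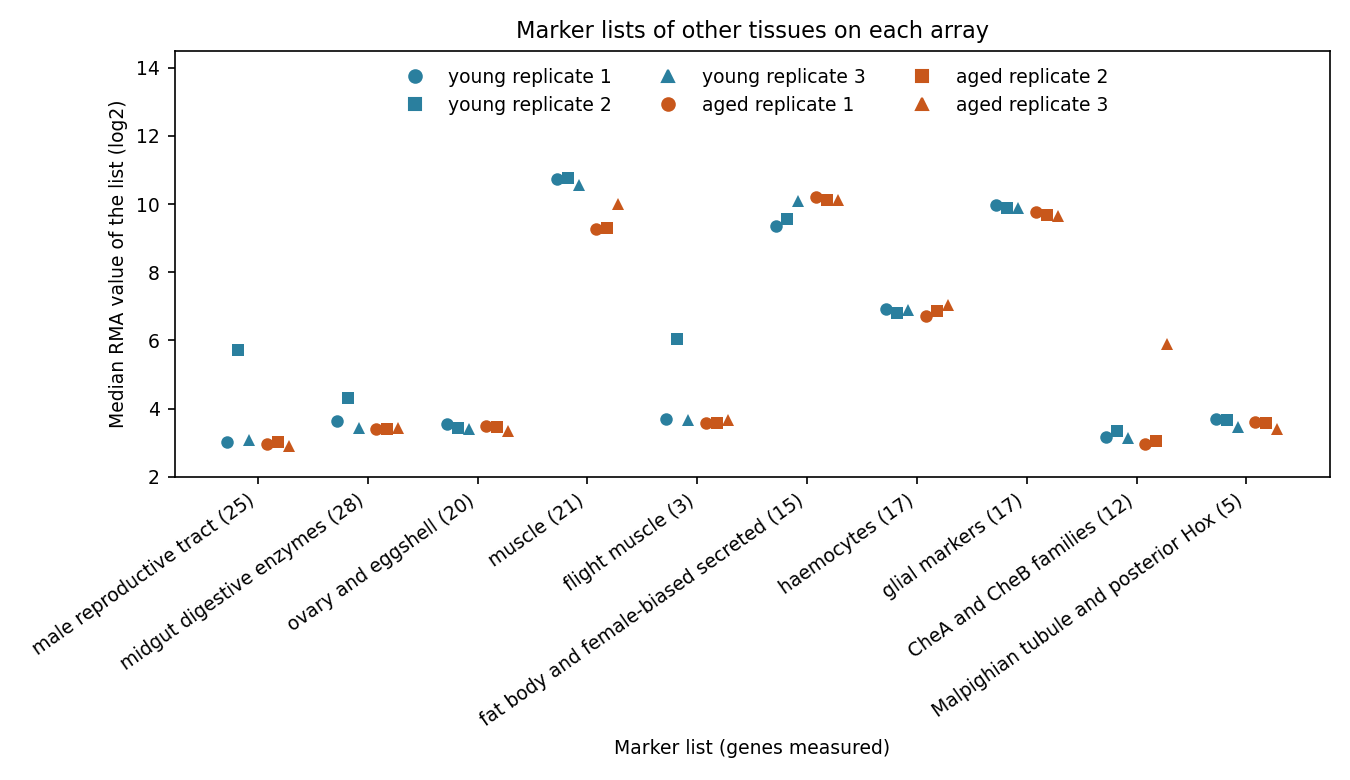
Median RMA value (log2, vertical axis) of marker lists of other tissues and of chemosensory CheA and CheB genes (horizontal axis, with the number of genes measured) on each array, blue for young and orange for aged, with a marker shape per replicate. Young replicate 2 stands apart in the male reproductive tract (5.73) and aged replicate 3 in the CheA and CheB families (5.89).

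In all, 14 of 27 tested lists shifted with camera's preset correlation of 0.01, 5 up and 9 down. With camera and an estimated correlation 0 lists passed at an adjusted p and 4 at an unadjusted p under 0.05, and 16 passed with fry. That test asks whether a list's genes move, on balance, 1 way and does not compare them with other genes.

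The last comparison asked whether RNA quality or labelling differed between the ages, from control transcripts with a probe set near each end. Over 5 fly control probe set pairs, for actin, GAPDH and eIF-4a, the mean 3' value exceeded the 5' value by 2.51 ± 0.14 on young arrays and by 1.99 ± 0.03 on aged arrays (log2, SD, n = 3), a difference of -0.52. All aged arrays lay below all young arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, so it cannot pass 0.05). Over 4 bacterial poly-A transcripts (dap, lys, phe and thr), which are spiked into samples as labelling controls, the excess was 1.86 ± 0.17 on young and 0.95 ± 0.08 on aged arrays, a difference of -0.90 (exact permutation p = 0.1). Their 5' probe sets were at 4.67 ± 0.13 on young and 5.89 ± 0.35 on aged arrays, and their 3' probe sets at 6.53 ± 0.12 and 6.84 ± 0.27. The 9 hybridization control probe sets averaged 3.15 on aged replicate 1 and 9.06 to 10.1 on the other 5 arrays.

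**Figure D4:**
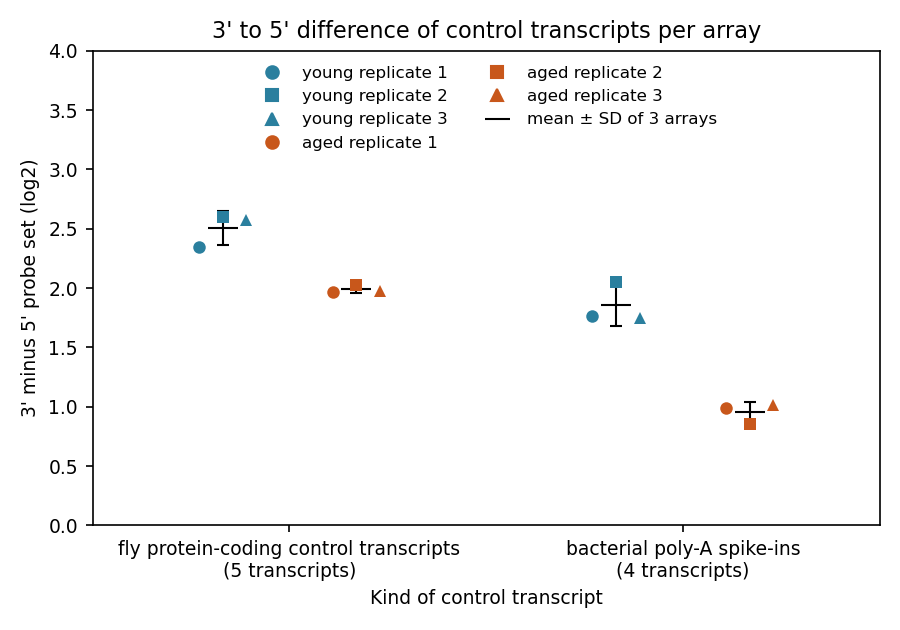
Difference between the 3' and the 5' probe sets of control transcripts (log2, vertical axis) on each array, for fly protein-coding control transcripts and bacterial poly-A spike-ins (horizontal axis); points are arrays, blue for young and orange for aged, and bars are the mean ± SD of 3 arrays. In both kinds the aged arrays lie below the young arrays, at 1.99 against 2.51 and at 0.95 against 1.86.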

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

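The tests of body tissue, leg tissue, flight muscle, RNA degradation and labelling as a cause of the control transcript pattern were chosen only after the result was seen. Both results that stood out here come from the control probe sets, which no gene comparison uses, though a labelling difference between the ages would reach the genes too. On aged arrays the 3' to 5' difference of the bacterial poly-A spike-ins was lower by 0.90 (value -0.9022), and their 5' probe sets were higher by 1.22.

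The 3' to 5' difference was smaller on aged arrays both in fly transcripts and in spike-ins. Degradation of fly RNA from young heads before spiking, as the whole cause, would leave the bacterial transcripts alike, and their shift of -0.9022, with all aged arrays below all young arrays, argues against it. A difference in labelling between the ages was not tested, since the spike-in value is part of the pattern, and labelling batch and age cannot be told apart. As the whole cause of the changed probe sets, labelling was tested on 136 genes with at least 2 changed probe sets, of which 108 (79.41%) had all of them changed in 1 direction, against 48.6% with shuffled directions. That share lay between the bounds set in advance for and against, so it decides nothing, and age itself stays open.

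Young replicate 2 stood above the other young arrays in male reproductive tract genes (median excess 2.37, 25 of 25 genes higher) and in midgut genes (median excess 0.4918, 21 of 28 higher), with Ebp at 9.72 against 3.16 and betaTry at 8.12 against 3.70, and in the flight muscle genes fln (6.04 against 3.68) and TpnC4 (5.82 against 2.60). Dim probe sets had a median excess of -0.06857, which met the bound set in advance against an array-wide rise of them. It decides nothing, since normalization to a common distribution holds such a median near 0. Body tissue among the heads is an untested hypothesis, since the male tract, midgut and flight muscle values are the pattern itself. Of these genes, 24 of the 28 midgut and 24 of the 25 male tract genes lay below the median level on the other young arrays. For Malpighian tubules the median excess of 0.007624 met the bound set in advance against them. It is left undecided here, a reading chosen after that value was seen, because only 5 genes were measured, 3 of them near background; biological causes were not tested.

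Aged replicate 3 stood above the other aged arrays in 12 of 12 CheA and CheB genes (median excess 2.11), with CheA75a at 9.35 against 4.69, and in 18 of 21 muscle genes (median excess 0.5758), with TpnC41C at 10.3 against 9.14. For abdominal tissue, the median excess of -0.01875 over midgut and male tract genes met the bound set in advance against it. These genes did rise on young replicate 2. Such tissue cannot be excluded, since the genes are near background here and the labels do not give the sex of the flies. Flight muscle stays open, since fln and TpnC4 had a mean excess of 0.05041 but Act88F an excess of 0.68. Leg tissue among the heads is an untested hypothesis, since the muscle and CheA values are the pattern itself, and 19 of the 21 muscle genes are at or above the median level on the other aged arrays too. No biological explanation was tested for a single array.

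Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real split itself, reached its count of changed probe sets (4071, against 0 at most in the other splits), and likewise 1 for 2-fold changes (292, against 0). With 10 splits no share under 0.05 can be had, so the splits are too few for that. At an unadjusted limma p under 0.05 the real split had 6621 probe sets and the others 217 to 664. Each of the other splits mixes the ages, so a difference between the ages widens its spread and lowers its count. These counts are therefore no measure of what chance gives. The hybridization controls of aged replicate 1, at 3.15, and the 18S rRNA probe sets, at 8.25 to 11.1 over the arrays, also differed between arrays.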

How the results depend on the processing

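The tests without young replicate 2 and aged replicate 3, with restored families, without _s_at and _x_at probe sets alone and with other control transcripts were chosen after the data were seen. The count of changed probe sets was 2302 to 4027 with 1 array left out (higher 1377 to 2371, lower 925 to 1659, at least 2-fold 275 to 314, lists 13 to 17, and 3' to 5' difference -0.60 to -0.47). It moved by over 1.5 times without aged replicate 1 (2302, of which 2273 were among the 4071) and without aged replicate 2 (2432, 2391 shared), with fewer arrays in the fit. Without young replicate 2 and aged replicate 3 it was 2492 (1462 higher, 1030 lower, 2221 shared). A test against the 2-fold threshold, a stricter question, left 59 of 292. No list passed with an estimated correlation (0 of 27 at an adjusted p, 4 at an unadjusted p), where adjusted p began at 0.102. The 3' to 5' difference was -0.38 with 18S rRNA added and -0.90 with the bacterial spike-ins. In all other settings the counts stayed within 1.5 times, at 2849 to 4926 changed probe sets and 13 to 18 lists, and no named gene turned its direction while past the threshold. Quantile normalization gave 53.4% higher and median centring 48.8%. Of the 102 named genes, 14 lost their call with at least 1 array left out and 85 kept it whichever array was left out. Of the 102, 4 lost it with centring, 3 with quantile normalization, 1 with limma-trend and 12 without young replicate 2 and aged replicate 3 together. Male tract genes also did not pass with fry (adjusted p = 0.423) or without both arrays (0.160). The midgut list, at adjusted p = 0.0508, passed in several settings (down to 0.00291 without young replicate 3). Pairing of arrays by replicate number was not clear. Deviations of same-numbered arrays correlated at 0.103, -0.019 and -0.056. The arrays numbered 1 correlated best with each other, but this did not hold for those numbered 2 or 3. With 3 arrays per age this check cannot exclude pairing. With the replicate block 3343 probe sets changed, 3170 of them among the 4071, 15 lists passed, and 8 named genes lost their call. These were DnaJ-1, Hsc70-4, Keap1, Atg3, RpS18, Jarid2, Act79B and VhaAC45RP, with limma adjusted p = 0.0505 (RpS18) to 0.0745 (Jarid2). Signal over background limits the dim probe sets: 621 of the 4071 lay below the median level.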

Other observations

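All lists in this part were added, and their tests chosen, after the data were seen, and their adjusted p-values run over the fixed and added lists together. Genes of chitin metabolism went both ways. Of 40 genes of chitin synthesis, deacetylation and binding, 7 rose, 15 fell and 18 did not pass (camera adjusted p = 0.00358, and adjusted p = 0.265 with an estimated correlation). This list, written after the data were seen, holds Vajk3 and Vajk2, which are among the 10 largest falls of all named genes. Its test is therefore not independent support. The Vajk genes Vajk3 (-4.11) and Vajk2 (-3.66), the chitin deacetylase gene serp (-2.28 ± 0.09), the chitin-binding protein gene Gasp (-1.86 ± 0.10) and the chitin synthase gene kkv (-0.98 ± 0.12, below the median level at both ages) fell. Among the 7 that rose, 5 were Idgf genes, which encode chitinase-like growth factors, from Idgf6 (0.38 ± 0.07) to Idgf1 (0.65 ± 0.07), and the others were the chitinase gene Cht5 (0.42 ± 0.09) and knk (0.42 ± 0.11). Of 35 glutathione S-transferase genes, 12 rose, 3 fell and 20 did not pass (camera adjusted p = 0.0172, and adjusted p = 0.265 with an estimated correlation). GstZ2 (0.92 ± 0.07) and GstO1 (0.71 ± 0.07) rose, and GstE14 (-0.94 ± 0.08), GstE13 (-0.65 ± 0.07) and GstD11 (-0.40 ± 0.12) fell. The proteasome with its core particle had 37 genes, of which 22 rose, 0 fell and 15 did not pass (camera adjusted p = 4.06e-05, and adjusted p = 0.265 with an estimated correlation).

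Of 69 mitochondrial ribosomal protein genes, 0 rose, 8 fell and 61 did not pass, with mRpS9 (-0.49 ± 0.07), mRpL55 (-0.49 ± 0.08) and mRpS14 (-0.43 ± 0.08) falling most (camera adjusted p = 0.00358, and adjusted p = 0.702 with an estimated correlation). Most vacuolar ATPase genes did not pass, and those that fell did so by small amounts. Of 31, 0 rose, 5 fell and 26 did not pass (camera adjusted p = 0.00883, and adjusted p = 0.353 with an estimated correlation). Those that fell were Vha44 (-0.54 ± 0.06), VhaAC45RP (-0.33 ± 0.08), Vha14-1 (-0.31 ± 0.06), Vha55 (-0.30 ± 0.06) and Vha26 (-0.27 ± 0.06). VhaAC45RP no longer passed without young replicate 3 or aged replicate 1 or 3 (adjusted p = 0.0611 to 0.0677), nor Vha14-1 without aged replicate 1 or 2 (0.0577 and 0.0609). Without young replicate 2 and aged replicate 3 together, VhaAC45RP (0.0561) and Ir68a (0.0544) did not pass. Of 109 ionotropic and gustatory receptor genes, 3 rose, 3 fell and 103 did not pass (camera adjusted p = 0.353). The related receptor genes Ir75a (2.42) and Ir75b (1.68 ± 0.12) rose and Ir68a (-0.64 ± 0.12) fell. For Ir75b and Ir68a the lower level lies below the median of all probe sets, so their differences are lower bounds. The other 3 that passed, Ir47a, Ir64a and Gr2a, lay below the median level at both ages, near background, so their differences are not given. Of 12 CheA and CheB genes, CheA87a rose and 11 did not pass (camera adjusted p = 0.320). Of 3 flight muscle genes, Act88F fell, and fln and TpnC4 did not pass. The median difference of that list was -0.9952, and -0.08 without young replicate 2, on which it stood at 6.04 against 3.56 to 3.71. Of 5 tubule genes Oatp58Dc fell (-0.46 ± 0.07) and 4 did not pass.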
